A study of Mus musculus with 6 samples.

How the data were processed

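Genomic DNA of mouse malignant mesothelioma, a tumour of the lining of the body cavities, was measured by array comparative genomic hybridisation, in which labelled tumour DNA and labelled reference DNA compete for the same probes. Per the labels, tumour DNA carried Cy5 and DNA of C57BL/6J mice carried Cy3 on every array, with no dye swap, so a positive ratio means more copies in the tumour. The 6 arrays came from 5 tumours, named ARF-104, ARF-110, ARF-112, ARF-128 and ARF-129. ARF-110 and ARF-128 were hybridised to a sparser design of 44050 spots, and ARF-104, ARF-112, ARF-129 and ARF-128 again to a denser design of 243301 spots. The denser array of ARF-128 is titled ARF-128PlusMinus, and what the addition means is not given in the sources used here. The 2 arrays share a source name and were counted as 1 tumour, represented by the denser array unless stated, although they correlated less (r = 0.56 over bins) than ARF-104 with ARF-129 (0.59). The labels describe primary mesothelioma cells except for ARF-104, whose labels give no cell type, and the study's own description speaks of 4 Arf(+/-) mice where the titles name 5 tumours, so the genotype is given for 4 and which title lies outside them is not known. All 5 form a single group, so no comparison between groups exists, and the labels' numbers were taken to mean separate animals.

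Per the file headers, the authors scanned the arrays and made the processed red and green intensity of each spot with Agilent Feature Extraction 8.5.1.1 on the sparser design, and with 9.1.3.1 (ARF-104, ARF-112, ARF-129) or 9.5.3.1 (ARF-128) on the denser one, using spatial detrending and 1 linear dye factor per channel. The log10 ratio of each spot in the files follows the processed red over green intensity closely, but does not equal it at every spot. The 2 correlated at r = 0.995 in ARF-129 and 0.998 in ARF-104, and more closely on the other arrays. The deposited value table of the series holds the same ratios as log10 values for the sparser design and as log2 values for the denser one, which was established by setting each column against its array. Its column medians were 0 and 0.0185 on the sparser design, and 0.0200, 0.0232, 0.0317 and 0.0491 for ARF-104, ARF-112, ARF-129 and ARF-128, so the table had not been centred, and nothing of its scale or direction stayed open. Coordinates are mm7, stated in the header of 1 denser-design file and used for all probes through the 41925 probe names that both designs share. The build of the sparser design is not given in the sources used here.

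The median red intensity of the spots before processing was divided by the median red background. The ratio was 11.1 for ARF-104, 10.7 for ARF-112, 9.27 for ARF-129, 5.80 for ARF-110, and 4.14 (denser) and 6.38 (sparser) for ARF-128. The probe noise, an SD of log2 ratios from neighbouring probes, was 0.15 in ARF-110, 0.36 in ARF-104, 0.39 in ARF-112, 0.49 in ARF-129, and 0.78 (denser) and 0.43 (sparser) in ARF-128. The median distance between autosomal probes was 7850 bp on the denser and 21614.5 bp on the sparser design. The number of arrays limits the precision of every mean.

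For each probe the log2 ratio of processed red over green intensity was taken, control spots and spots marked as outliers in the deposited files were left out, repeated probes were averaged, and each array was centred on its autosomal median. Chromosomes were segmented by penalised least squares (PELT, penalty 5 log n, at least 5 probes), and a segment with a mean at or past 0.25 in either direction was called gained or lost. Autosomes were also divided into bins of 1 Mb, of which 2179 had a value in every tumour. Recurrence was defined as a call in at least 3 tumours and tested, one-sided, by a permutation test that rotated each tumour's called genome around the joined autosomes 10000 times (2000 times for alternatives). Mean ratios of bins and of genes were tested against 0 with limma 3.58.1 (an intercept, eBayes, Benjamini-Hochberg adjustment), which leaves out the spread of the reference DNA. Chromosome means were tested with an exact two-sided sign-flip permutation test, in which at least 2 of the 32 sign patterns of 5 tumours are as extreme as the data, so none can pass 0.05. Other tools were R 4.3.3, statmod 1.5.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9.

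A gene's value was the mean of its own probes, and its call came from the segments over it. Of 25707 gene names in the files, 15421 were matched by accession, 435 by symbol and 252 by synonym to a table of the GRCm38.p6 assembly used for names only, and 9599 were kept as the files give them.

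The lists, the naming rule and the tests of recurrence, bins, chromosomes, Faf1, Cdkn2a, tumour suppressor losses, oncogene gains and TNF/NF-kB losses were fixed before the data were examined. The tests of the other lists and directions and the counts of single genes by limma were added later. The named genes were the measured members of the target list (Faf1, Cdkn2a, Cdkn2b, Cdkn2c), the 6 members of each other list with the largest absolute mean, in the 5 losses and 5 gains shared by most tumours the 5 genes with the largest absolute mean and any list member, and in each tumour the 2 genes with the lowest and the 2 with the highest segment mean. Genes known only by a clone identifier are not printed. The other lists were tumour suppressors, the TNF/NF-kB pathway, oncogenes, neighbours of Faf1, Cdkn2a with its neighbours, fragile sites, genes often variable in copy number between mouse strains, immune receptors, and Y-linked and X-linked genes, 11 lists in all. None of 12 immune receptor genes was measured, and the Y-linked (4 of 10 measured) and X-linked genes (10 of 12) entered no test. Gene-by-tumour losses and gains of the 8 autosomal lists were tested by the same rotations. Of these 16 tests, 3 were among those fixed beforehand. Each tumour is rotated separately, which breaks up changes that tumours share at the same place. A list with genes at such a place can therefore pass for that reason alone.

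Changes were simulated in independent normal noise with the noise SD of each array. A change of 0.5 over 50 probes was found in 100% of 40 cases in ARF-110, 57.5% in ARF-104, 37.5% in ARF-112, 2.5% in ARF-129 and 0% on the denser array of ARF-128. Such noise holds no trend along the chromosomes, so these shares may differ in the data. A change of 1 over 40 probes was found in 100% of cases except on the denser ARF-128 array (12.5%). The limma step was run on 2179 bins and 19975 genes with 200 changed in each and independent noise. Of those changed by 0.5, 88.0% of bins and 0% of genes were recovered, and 99.5% and 83.5% of those changed by 1. In the data limma called far more genes (1321 lower and 1612 higher), which loosens the adjusted threshold. The simulated share for genes therefore does not carry over to the data. Of 100 sets made by rotating the tumours' own calls, the rotation test gave p under 0.05 in 5 for losses and 6 for gains. About that share follows from the construction, since the test uses the same rotations. It checks the computation only, and not whether rotation is a fair model of tumours without recurrence.

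Other settings, chosen beforehand, were normexp background correction, loess within arrays, centring on the mode, the deposited value table, leaving out dim probes, a penalty of 15 log n, thresholds of 0.15 and 0.4, bins of 500 kb, the sparser ARF-128 array, the mean of both ARF-128 arrays, the denser design alone, each tumour left out in turn, and the gene's median or segment mean. A correction for probe GC content and scan day as a random block were added after seeing the data. The headers give 3 scan days, 1 holding the sparser arrays, 1 holding ARF-104, ARF-112 and ARF-129, and 1 holding the denser ARF-128 array, so day, design and software version largely coincide. A block for day (duplicateCorrelation) had an estimated correlation of -0.13 over bins and 0.42 over genes. Of the arrays behind the means, ARF-110 and ARF-128 each stood alone on a day. The estimate thus rests on the day of ARF-104, ARF-112 and ARF-129. A shift shared within a day would make the correlation positive, so the block over bins does not allow for such a shift. With it limma called more bins, 63 lower and 118 higher against 14 and 85.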

Results

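Copy number was profiled in 5 mouse tumours in a study of mesothelioma in Arf(+/-) mice, which carry 1 inactivated copy of Arf, a product of the Cdkn2a locus that stabilises p53. The study's description gives this genotype for 4 mice, and which of the 5 lies outside them is not known. The study asked which imbalances recur in these tumours, and its title names Faf1, an adaptor protein that restrains TNF and NF-kB signalling. Ratios are log2 of tumour over C57BL/6J reference, and positions are mm7. Gain of 1 copy by every diploid cell would give 0.58 and loss of 1 copy -1.

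The tumours differed widely in how much of the genome was altered. ARF-129 was altered in 47.1% of autosomal bins, ARF-112 in 24.1%, ARF-104 in 18.3%, ARF-110 in 17.0% and ARF-128 in 9.68%. The mean was 23.2% ± 14.3 (SD, n = 5), with 13.5% ± 5.34 gained and 9.78% ± 11 lost. ARF-129 had 26.6% of bins lost, ARF-112 15.2%, ARF-110 4.04%, ARF-128 1.79% and ARF-104 1.19%, and without ARF-129 the mean lost share was 5.56%. ARF-128 was read on the noisiest array, where a change of 0.5 over 200 probes was found in 40% of simulated cases.

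**Figure D1:**
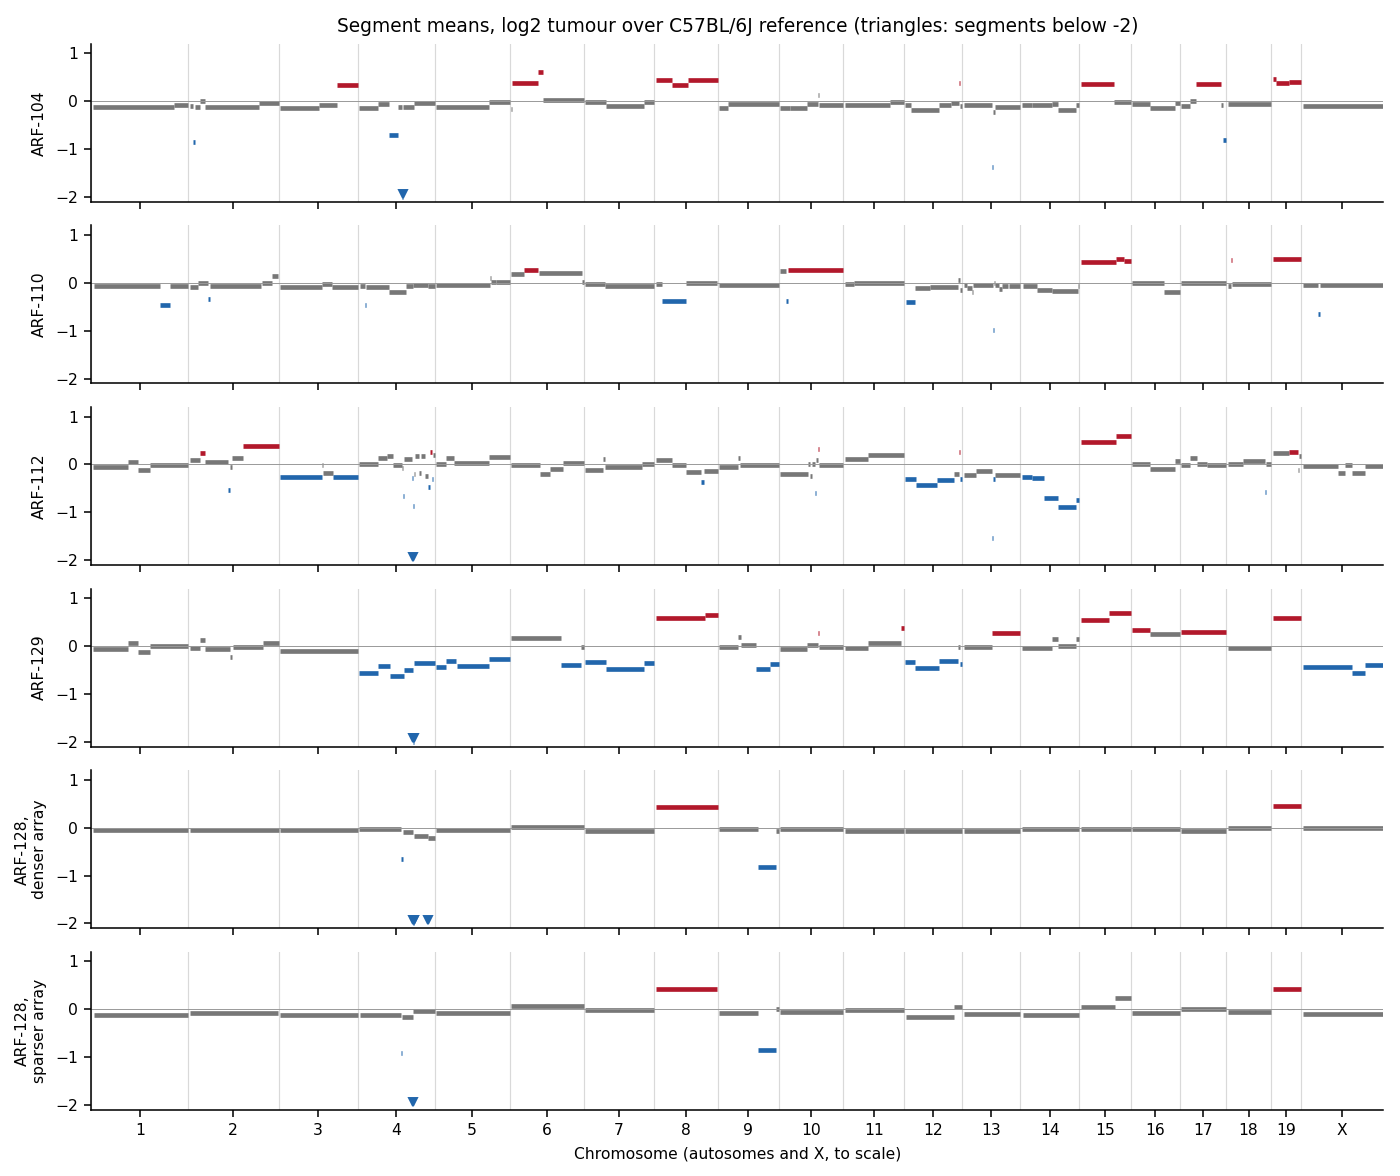
Segment means (log2 ratio, vertical axis) along the autosomes and X (horizontal axis, to scale) for the 6 arrays, with segments at or above 0.25 in red, at or below -0.25 in blue, others in grey, and triangles for segments below -2. The gain of chromosome 19 was seen in every panel, at 0.24 in ARF-112 and 0.58 in ARF-129.

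Chromosome 19 was higher in all 5 tumours. Its mean was 0.43 ± 0.13 (SD, n = 5), with 0.40 in ARF-104, 0.51 in ARF-110, 0.24 in ARF-112, 0.45 in ARF-128 and 0.58 in ARF-129. The stretch from 37083414 to 54839322 was called gained in all 5 and holds Chuk, an IkB kinase, Nfkb2, an NF-kB subunit, and Sufu, a repressor of Hedgehog signalling. Chromosome 15 was called gained in 4 tumours from 3004549 to 69226662, with chromosome means of 0.19 in ARF-104, 0.46 in ARF-110, 0.52 in ARF-112 and 0.62 in ARF-129 against -0.03 in ARF-128, whose sparser and less noisy array gave 0.16. That stretch holds Myc, a growth-promoting transcription factor, Sqle, an enzyme of cholesterol synthesis, and Mtss1, an actin-binding protein. Chromosome 8 was gained whole in ARF-104 (0.43), ARF-128 (0.44) and ARF-129 (0.60), but stood at -0.11 in ARF-110 and -0.07 in ARF-112. In ARF-110 the part from 15866718 to 64056406 was called lost (-0.38). It holds Ikbkb, another IkB kinase, and Fgfr1, a growth factor receptor. Gains of 3 tumours also overlapped in shorter stretches. The stretch on chromosome 10 ran from 79540860 to 81044968, with Stk11, a kinase upstream of AMPK (0.16 ± 0.13 on its own probes). That on chromosome 17 ran from 54127661 to 55360736. On chromosome 10 the gain itself was short in ARF-112 (0.32) and ARF-129 (0.28), but ran from 17538860 to 129866929 in ARF-110. On chromosome 17 it was short in ARF-112 alone (0.26), ran from 32730809 to 83140332 in ARF-104, and took in the whole chromosome in ARF-129.

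Gains recurred in 267 of 2179 bins, against a mean of 39.1 over rotations (permutation p = 0.0001, the smallest that 10000 rotations can give). Chromosome 8 held 116 of them, chromosome 15 93, chromosome 19 56, and chromosomes 10 and 17 held 1 each. Without ARF-104 the count was 150, without ARF-128 151 and without ARF-129 115, and the largest of these permutation p values was 0.000999. By limma, 85 bins were higher, 54 on chromosome 19, 30 on chromosome 15 and 1 on chromosome 12, and 14 were lower. Without ARF-104 or without ARF-110 limma called 0 bins in either direction, with 159 and 239 higher at an unadjusted p under 0.05 and 188 and 267 lower. Leaving out ARF-112 gave 54 higher and 0 lower bins (217 and 235 unadjusted), and leaving out ARF-129 gave 36 and 0 (139 and 219 unadjusted). In the exact sign-flip test, 2 of the 32 sign patterns gave a mean as far from 0 for chromosome 19, the fewest the design allows, and its p was 0.24 after Benjamini-Hochberg adjustment over 19 autosomes.

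**Figure D2:**
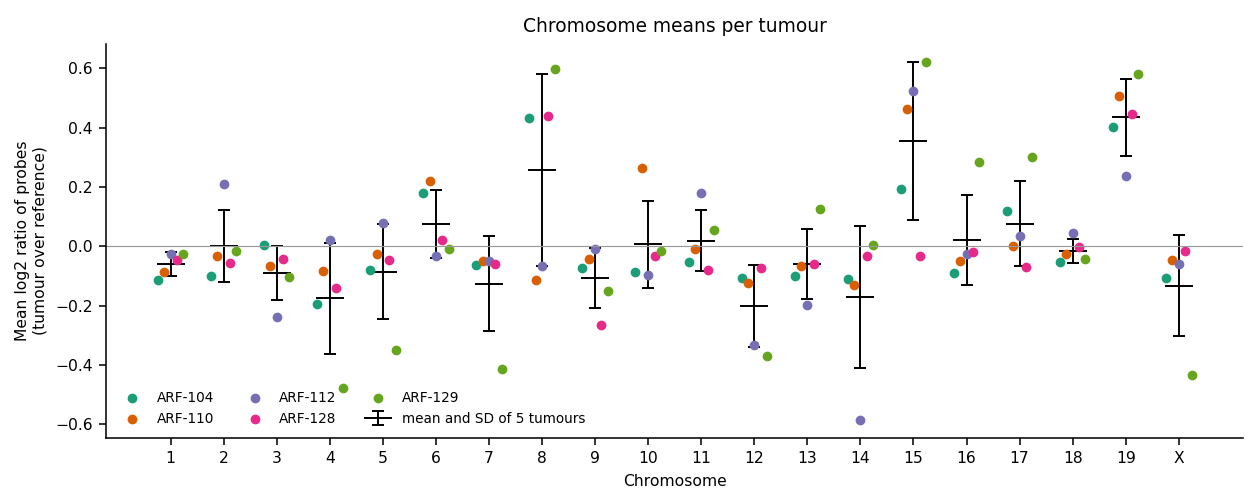
Mean log2 ratio of the probes of each chromosome (vertical axis) for the autosomes and X (horizontal axis), with a point per tumour and bars for the mean and SD of 5 tumours. Chromosome 19 lay above 0 in all 5 tumours, with a mean of 0.43, while chromosome 8 split between 0.60 in ARF-129 and -0.11 in ARF-110.

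Losses on chromosome 4 included Cdkn2a, which encodes the cell-cycle inhibitors p16 and Arf. The gene was called lost in 4 tumours. Its own probes stood at -3.30 in ARF-104, -1.10 in ARF-112, -1.08 in ARF-128 and -0.64 in ARF-129, against -0.14 in ARF-110 (mean -1.25 ± 1.21, SD, n = 5). ARF-110 was read on 2 Cdkn2a probes of the sparser design, and the other tumours on 4 of the denser design. In ARF-104 a stretch of 257 probes from 88569777 to 91849661 had a mean of -3.30, or 10.1% of the reference signal. The loss shared by 4 tumours ran from 88569777 to 89126594 and also took in part of Mtap, an enzyme of methionine salvage (-0.55 ± 0.62), and Dmrta1, a DM-domain transcription factor (-1.19 ± 0.81). Without ARF-104 the mean of Cdkn2a was -0.74.

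The limma adjusted p of Cdkn2a was 0.0585 over all genes, and ranged from 0.0240 to 0.267 over 17 alternatives. It fell below 0.05 without ARF-110 (0.0322), with the sparser ARF-128 array (0.0240) and with the mean of both ARF-128 arrays (0.0280). Normexp background correction lowered the number of tumours called lost to 1 and moved the mean to -0.42. Adjusted over the list alone, all 3 measured target genes passed, with 0.0153 for Cdkn2a, 0.0154 for Faf1 and 0.0118 for Cdkn2c. On segment means the limma adjusted p over all genes was 0.267 for Cdkn2a and 0.345 for both Faf1 and Cdkn2c. With scan day as a random block the adjusted p over all genes was 0.247 for Cdkn2a, 0.25 for Faf1 and 0.160 for Cdkn2c, and the smallest adjusted over the list alone was 0.0653. Whether a Cdkn2a probe lies in the inactivated part of the inherited allele is not given in the sources used here.

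Faf1 stood below 0 in all 5 tumours, at -0.67 in ARF-129, -0.32 in ARF-128, -0.28 in ARF-104, -0.21 in ARF-110 and -0.09 in ARF-112 (mean -0.31 ± 0.22, SD, n = 5; 109055389 to 109340377 on chromosome 4). Its segment was called lost only in ARF-129, where all of chromosome 4 was low (-0.48). In the other tumours the segment over Faf1 lay between -0.11 and 0.11, so the gene's own probes were lower than their surroundings. Cdkn2c, the neighbouring cell-cycle inhibitor gene, had a mean of -0.38 ± 0.18 on 2 probes (1 on the sparser design). The limma adjusted p of Faf1 was 0.0727, with a range of 0.0377 to 0.345 over 17 alternatives, and 0.0384 with the sparser ARF-128 array and 0.0377 with the mean of both. On segment means the value was -0.13 (adjusted p = 0.345), and normexp moved the mean to -0.09. ARF-110 had only 2 Faf1 probes against 41 on the denser design. In simulation a change of 0.5 over 50 probes was found in 57.5% of cases in ARF-104, 37.5% in ARF-112, 2.5% in ARF-129 and 0% on the denser ARF-128 array.

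**Figure D3:**
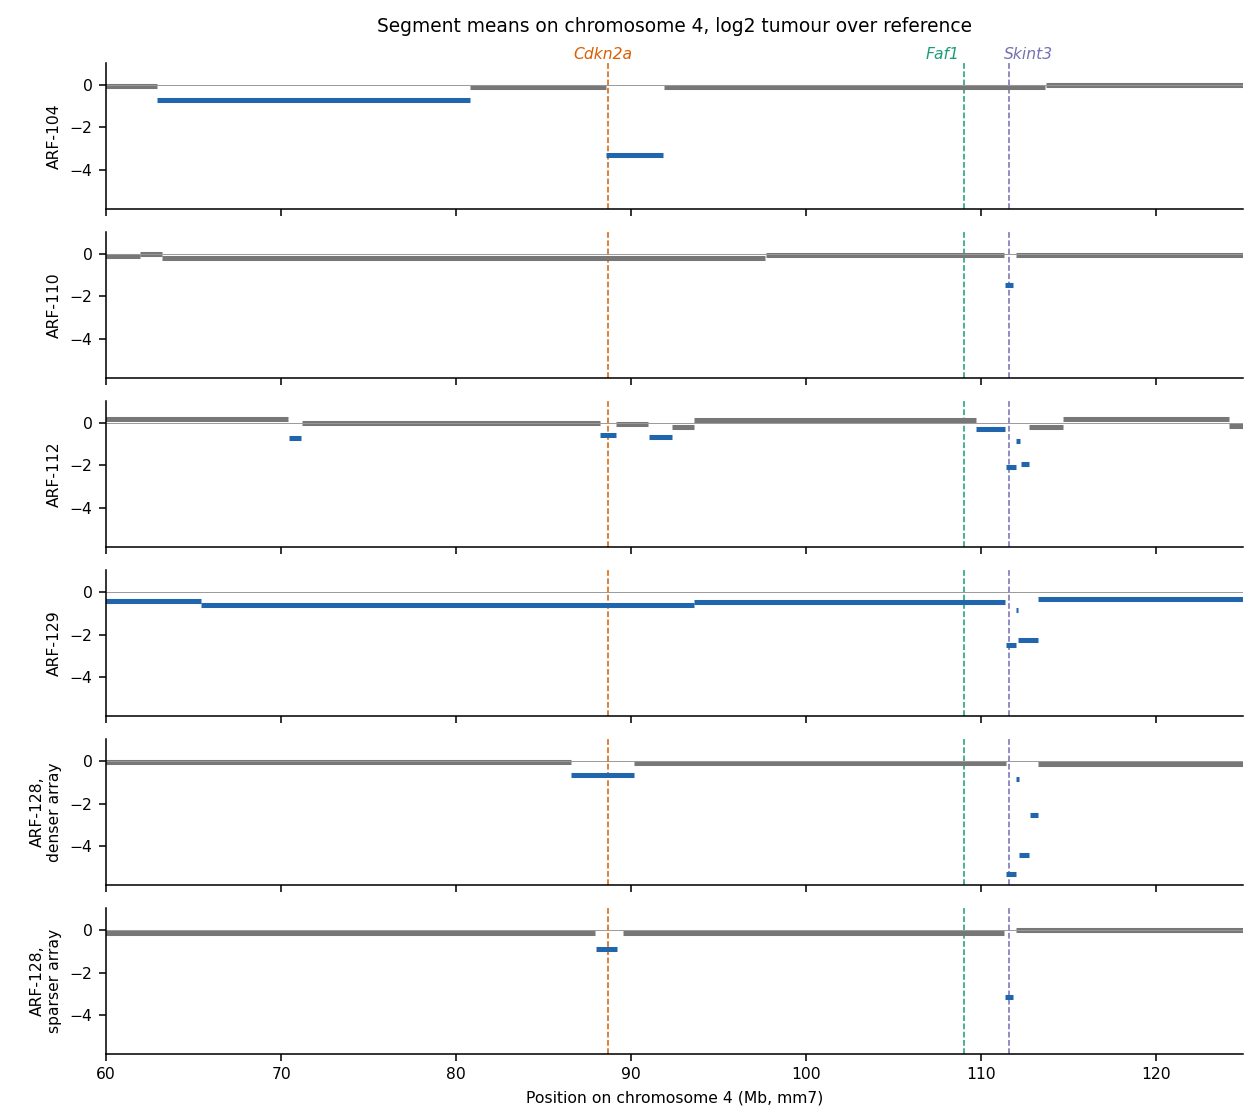
Segment means (log2 ratio, vertical axis) on part of chromosome 4 (horizontal axis, Mb, mm7) for the 6 arrays, with segments at or below -0.25 in blue and dashed lines at Cdkn2a, Faf1 and Skint3. The segment over Cdkn2a reached -3.30 in ARF-104, and the segment over Skint3 lay at -5.30 in ARF-128.

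Deep losses also lay over Skint genes, a family related to butyrophilins, on chromosome 4 from 111458080 to 111917055. Skint3 stood at -1.39 in ARF-110, -2.08 in ARF-112, -5.23 in ARF-128 and -2.73 in ARF-129, but at -0.23 in ARF-104 (mean -2.33 ± 1.87, SD, n = 5). On chromosome 14, from 64121782 to 64327455, Entpd4, a Golgi nucleotidase, was low on its own probes in all 5 tumours (-1.16 ± 0.12), as was Loxl2, a collagen-modifying enzyme (-0.99 ± 0.17), while segments over them were called lost in 4, not in ARF-128. The limma adjusted p was 0.0345 for Skint3, 0.00703 for Entpd4 and 0.0121 for Loxl2. With scan day as a random block it was 0.0924, 0.0219 and 0.0474. Normal DNA of the same mice was not analysed here.

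Losses recurred in only 19 bins, 14 on chromosome 12 and 5 on chromosome 4, against a rotation mean of 7.19 (permutation p = 0.123). Chromosome 12 was low in ARF-112 (-0.33) and ARF-129 (-0.37), and ARF-110 shared its start, from 3828700 to 22506320. The count fell to 6 without ARF-110, 2 without ARF-112 and 1 without ARF-129. It reached permutation p = 0.00450 at a threshold of 0.15, with 121 bins, and at the same p under normexp, with 2 bins.

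Among tumour suppressors, 18 of 120 gene-by-tumour pairs were lost (rotation permutation p = 0.0386, and 0.116 after adjustment over the 3 planned list tests). Cdkn2a and Mtap were lost in 4 tumours each, Rassf1, a Ras-association protein, and Sav1, a Hippo-pathway scaffold, in 2 each. Segments over Bap1, a deubiquitinase, Lats2, a Hippo kinase, Rb1, the retinoblastoma gene, Fhit and Ptch1 were called lost in ARF-112 alone, and that over Cdkn2c in ARF-129. In ARF-112 the genes' own probes stood at -0.82 for Lats2, -0.77 for Rb1 and -0.31 for Fhit, but at -0.13 for Bap1 and -0.08 for Ptch1. Bap1 was lower in ARF-128 (-1.08, and -0.99 on its sparser array), where its segment was not called, and the probes of Sav1 stood at 0.05 in ARF-112 and 0.25 in ARF-129. Without ARF-112 the count was 10 (p = 0.303 by permutation), without ARF-104 16 (0.0945) and without ARF-128 15 (0.120), but 18 without ARF-110 (0.0190) and 13 without ARF-129 (0.0005, the smallest that 2000 rotations can give). By limma 1 of 24 tested members was lower, Cdkn2c, read by 2 probes on the denser design and 1 on the sparser. In ARF-112 its probes stood at -0.55 under a segment at 0.11, and on segment means its limma adjusted p was 0.345. The 2 higher members were the Wnt antagonist Dkk1 (0.62 ± 0.16, 1 probe) and Sufu (0.38 ± 0.13). The counts adjusted over the list alone were also 1 and 2. With scan day as a random block the adjusted p was 0.0696 for Dkk1 and 0.111 for Sufu, and adjusted over the list alone 0 members were lower (3 unadjusted) and 1 was higher.

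In the TNF/NF-kB list, 13 of 145 pairs were lost (permutation p = 0.540), 9 of them in ARF-129. Gains made up 34 pairs in 12 genes (permutation p = 0.00290, and 0.0232 after adjustment over 8 lists), a direction that was not planned as a test. Chuk and Nfkb2 were gained in 5 tumours, Rela and Fas in 4, Tradd, Ikbkb and Cyld in 3, Tnf and Nfkbie in 2, and Traf2, Nfkb1 and Tnfaip3 in 1. These include kinases and subunits that transmit the signal (Chuk, Ikbkb, Rela, Nfkb1, Nfkb2), receptor-side proteins (Fas, Tradd, Traf2), the ligand Tnf, and the inhibitors Cyld, Nfkbie and Tnfaip3. The genes gained in most tumours lie on chromosomes 19 and 8. The rotations do not keep the shared gains of these chromosomes in place. The permutation p of the gains therefore cannot separate the pathway from those chromosomes. Of 26 members tested by limma, Tnf (0.53), Tradd (0.58) and Nfkbie (0.49) were higher and the NF-kB inhibitor Nfkbia was lower (-0.76), with the same counts adjusted over the list alone. On segment means none of these 4 passed (limma adjusted p of 0.278, 0.267, 0.338 and 0.20), and the 4 members that did were all higher. With scan day as a random block the limma adjusted p was 0.0920, 0.136, 0.140 and 0.0997, and the smallest adjusted over the list alone was 0.0783.

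The oncogene list had 19 of 170 pairs gained (permutation p = 0.905) and 18 lost (0.257). Myc and Fosl1, an AP-1 subunit, were gained in 4 tumours each, and Fgfr1, a growth factor receptor, in 3. By limma 4 members were lower and 1 higher, over all genes and adjusted over the list alone. Fosl1 was the higher one (0.51 ± 0.18). Mdm2, which degrades p53, was among the lower ones (-0.66 ± 0.53), but the segment over it had a mean of 0.03, and on the sparser design its probes stood at 0.26 in ARF-110 and -0.24 in ARF-128. The limma adjusted p was 0.0905 for Fosl1 and 0.148 for Mdm2 with scan day as a random block, and the smallest adjusted over the list alone was 0.134.

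The target list carried 6 losses in 15 pairs (permutation p = 0.0245, and 0.0653 adjusted over 8 lists), or 3 without ARF-129 (0.0935) and 1 under normexp (0.0700). The list of Cdkn2a and its neighbours carried 21 losses in 45 pairs, 4 of them of Cdkn2a itself and counted in the target list too (permutation p = 0.00200, adjusted 0.00840), with 12 without ARF-129 (0.00600) and 4 under normexp (0.0375). Neighbours of Faf1 carried 18, of which 16 were in ARF-129 (permutation p = 0.0671, adjusted 0.0895). Fragile-site genes such as Immp2l and Ptprd carried 10 (permutation p = 0.0632, adjusted 0.0895). Genes often variable between mouse strains carried 25 losses in 120 pairs (permutation p = 0.00210, adjusted 0.00840), with Skint3, Skint4, Skint9 and Entpd4 in 4 tumours each, and 14 without ARF-129 (0.00300). For gains the permutation p was 0.0850 for tumour suppressors (23 pairs), 0.0987 for fragile sites (14) and 0.592 for strain-variable genes (16), with 0 gains in the other 3 lists. By limma, adjusted over the list alone, 2 genes of the Cdkn2a list (Dmrta1 and Cdkn2a itself), 3 neighbours of Faf1, 0 fragile-site genes and 6 strain-variable genes were lower, and 1 strain-variable gene was higher. Over all genes the counts were 1, 2, 0 and 6 lower and 1 higher (fragile sites had 1 lower and 1 higher at an unadjusted p under 0.05). With scan day as a random block limma called 0 genes of the Cdkn2a list (1 lower unadjusted), 0 neighbours of Faf1 (4 lower unadjusted) and 0 fragile-site genes (0 unadjusted), over all genes and adjusted over the list alone. Of strain-variable genes it called 1 lower over all genes, Entpd4, and 6 lower and 1 higher adjusted over the list alone.

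**Figure D4:**
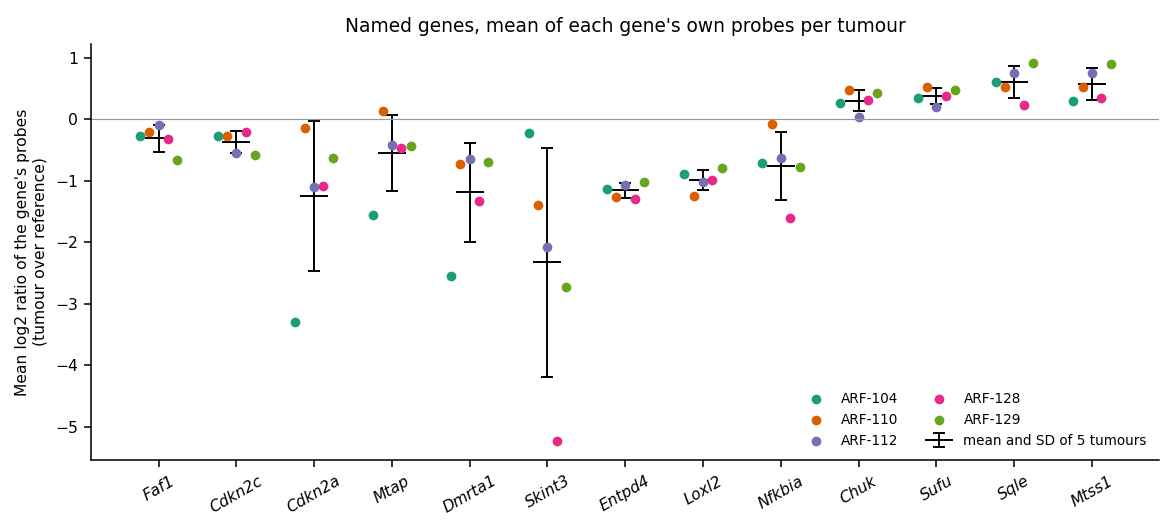
Mean log2 ratio of each gene's own probes (vertical axis) for 13 named genes (horizontal axis), with a point per tumour and bars for the mean and SD of 5 tumours. Entpd4 had the narrow range of -1.31 to -1.02, while Cdkn2a spread from -3.30 to -0.14.

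Over single genes limma called 1321 lower and 1612 higher of 19975. Named genes with high values in most tumours were Cox6c, a subunit of cytochrome c oxidase (1.34 ± 0.51), and Osr2, a transcription factor (1.24 ± 0.45), each read by 1 probe on chromosome 15 and high also in ARF-128 (1.21 and 1.62, and 1.18 and 0.54 on its sparser array), where the chromosome was not gained. Values were lower for Sqle (0.60 ± 0.26) and Mtss1 (0.56 ± 0.26). On chromosome 10, Fstl3, an activin-binding protein (0.75 ± 0.15), and Jsrp1 (0.93 ± 0.36) were high, while Timm13, a mitochondrial import protein read by 1 probe in the same stretch, stood at -0.65 ± 0.60. The segment over these 3 had a mean of 0.19 (limma adjusted p = 0.212) and lay at -0.03 in ARF-128, where Fstl3 stood at 0.57 and Jsrp1 at 0.88. The limma adjusted p of Cox6c, Osr2, Sqle, Mtss1, Fstl3 and Jsrp1 was 0.0125 to 0.0207, and 0.0607 to 0.104 with scan day as a random block. Myc itself, read by 1 probe, had a mean of 0.59 ± 0.69 (limma adjusted p = 0.107), with -0.61 in ARF-128 but 0.50 on that tumour's sparser and less noisy array. With scan day as a random block limma called 3 lower and 3 higher genes, among them Entpd4 and Loxl2 as lower and Marveld1, a membrane protein on chromosome 19 (1.25 ± 0.21, 1 probe), as higher. With segment means it called 0 lower (1844 unadjusted) and 822 higher. Without ARF-104, ARF-112 or ARF-129, limma called 0 genes in either direction, with at least 2356 lower and 2528 higher at an unadjusted p under 0.05.

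The 2 arrays of ARF-128 correlated at r = 0.56 over 2179 bins, which are not independent replicates. Other pairs of arrays ranged from 0.08 to 0.59, and ARF-104 with ARF-129 was the highest. Both ARF-128 arrays carried the gains of chromosome 8 (0.44 and 0.41) and chromosome 19 (0.45 and 0.43) and the losses over Cdkn2a (-0.66 and -0.92 as segment means). No pair was negative, so the arrays gave no sign of opposed dye direction.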

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

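No test in this part was chosen after the results were seen. The rule for naming genes, however, picks extreme values of these same data, some within 1 tumour. Of 100 values set against their spread over tumours, 12 had 1 tumour far from the others. Independent values not picked for size would give about 1 in 20, or 5, by chance. Genes were picked for size and share changes with their chromosomes, so 12 cannot be read against 5. Of the 12, ARF-129 accounted for 5, ARF-112 for 3, ARF-110 for 2, and ARF-104 and ARF-128 for 1 each.

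Whole chromosomes accounted for 6 of these values. ARF-129 was low on chromosome 7 (-0.41, the others between -0.06 and -0.05) and on X (-0.43, the others between -0.11 and -0.02), and high on chromosome 16 (0.29, the others between -0.09 and -0.02). ARF-112 was high on chromosome 2 (0.21) and low on chromosome 14 (-0.59). ARF-110 was high on chromosome 10 (0.26).

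Single genes gave the other 6. Elavl2, an RNA-binding protein gene inside the deep deletion of ARF-104, stood at -3.31 there and between -0.71 and 0.05 elsewhere. Rnf11, a ubiquitin ligase gene near Faf1, stood at -0.78 in ARF-129, and Atrx, a chromatin remodeller on X, at -0.71 in the same tumour. Nfkb2 stood at -0.62 in ARF-128 on 1 probe of its denser array, but at 0.41 on its sparser array, near the other tumours (0.44 to 0.69), and the segment over it was called gained, so the low value was not repeated. Mdm2 stood at 0.26 in ARF-110, read on the sparser design, and between -1.05 and -0.76 on the denser arrays of the other 4 tumours. It stood at -0.24 on the sparser array of ARF-128, so part of the difference goes along with the array design. In ARF-110 Mdm2 also lay in a called gain of chromosome 10 (segment mean 0.27). The shares of the design and of this gain were not tested. Prss1, a trypsinogen gene read by 1 probe on the denser design, stood at 0.62 in ARF-112 and between 0.99 and 1.01 in the other 3 tumours measured.

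Outside the comparisons, mitochondrial probes of the denser design (2, of which ARF-112 had 1) had a mean of 4.11 ± 0.24 (SD, n = 4), which is far more signal from tumour than from reference DNA. No explanation of it was tested.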

How the results depend on the processing

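The GC correction and the scan-day block were chosen after the data were seen, as were all alternatives for the target, Cdkn2a-with-neighbours and strain-variable losses, the TNF/NF-kB gains and the counts of genes; the other alternatives were planned. For the comparisons, 154 values under alternatives kept their direction, their side of the threshold and, for sizes, stayed within 1.5 times or the spread, 58 moved, 8 newly passed the threshold and 6 no longer did. Altered share ranged from 11.9% to 31.7% over 18 alternatives, within 1 SD (14.3) of its mean, and the repeat correlation from 0.50 to 0.59 over 7. Across the list tests p came from the rotation permutation test. TNF/NF-kB gains had permutation p between 0.00100 and 0.0400 over 17. Oncogene gains had p between 0.777 and 0.961 over 17. Gained bins stayed past the threshold in all 18. Unless stated, the cause of a change was not tested.

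Normexp gave 2 bins lost (permutation p = 0.00450), 2 tumour suppressor losses (0.225), 1 target loss (0.0700), 4 losses in the list of Cdkn2a and its neighbours (0.0375), 1 TNF/NF-kB loss, 3 bins lower by limma and 470 genes lower. Loess gave 8 bins lost, 3 autosomes with 1 sign in every tumour (5 in the main setting), 324 genes lower and 764 higher. Centring on the mode gave 31 bins lost, 18 tumour suppressor losses (permutation p = 0.0875), 8 autosomes with 1 sign and 53 bins higher. The penalty of 15 log n gave 15 tumour suppressor losses (permutation p = 0.130). The threshold of 0.15 gave 121 bins lost (permutation p = 0.00450). The threshold of 0.4 gave 5 bins lost, 10 oncogene gains and 6 TNF/NF-kB losses, with 13 tumour suppressor losses (permutation p = 0.00200). Bins of 500 kb, which are more numerous by construction, gave 32 bins lost, 484 gained, 42 lower and 153 higher. Segment means gave 0 genes lower and 822 higher.

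The denser design alone, with 4 tumours, gave 6 bins lost, and 0 bins lower and 0 higher by limma (267 and 239 unadjusted). It gave 2631 genes lower and 2807 higher, and Cdkn2a at -1.53 (limma adjusted p = 0.0322). These are the same arrays as without ARF-110, a single check that enters the counts of alternatives under both names. The design and that tumour cannot be told apart. The sparser ARF-128 array gave 82 bins lower, 2228 genes lower and 2964 higher, Faf1 at -0.32 (0.0384) and Cdkn2a at -1.22 (0.0240). The mean of both ARF-128 arrays gave 45 bins lower, 2516 genes lower and 2916 higher, Faf1 at -0.32 (0.0377) and Cdkn2a at -1.24 (0.0280). The scan-day block, whose correlation over bins was negative (-0.13), gave 63 bins lower, and 3 genes lower and 3 higher.

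Leaving out 1 tumour at a time gave 1 to 17 bins lost, 115 to 251 gained, 0 to 13 lower and 0 to 108 higher by limma, 0 to 2631 genes lower and 0 to 2807 higher, 6 to 9 autosomes with 1 sign, 10 to 18 tumour suppressor losses, 4 to 13 TNF/NF-kB losses, 14 to 17 oncogene gains, Faf1 at -0.37 to -0.23 and Cdkn2a at -1.53 to -0.74.

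The sign turned for 5 genes. The gene median gave Fgfr1 -0.00409, and segment means gave Mdm2 0.0259, Cdk4 0.0259, Ifnb1 -0.32 and Timm13 0.19. Of the other comparisons of named genes, 737 stayed on their side of the threshold, 161 no longer passed it and 49 newly did. The denser array of ARF-128 had the lowest red signal over background (4.14) and the highest probe noise (0.78), and shorter changes were missed there in simulation. No paired analysis was possible because all 5 tumours form a single group.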

Other observations

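The tests of probe failure, of an inherited deletion and of the reference's copies of chromosome 19, the correlation of gene deviations between tumours, and the allowance of 1 SE around the bounds for Faf1, were chosen only after the results were seen.

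Large events in single tumours added to the shared ones. ARF-128 lost chromosome 9 from 82123751 to 118347323 (-0.82, and -0.85 on its sparser array), a stretch that holds Rassf1. ARF-112 lost the far part of chromosome 14, at -0.69 from 47090888 to 75490179, where Rb1 and Lats2 lie, and -0.90 from 75511391 to 112361849. ARF-129 had low means on chromosomes 4 (-0.48), 5 (-0.35) and 7 (-0.41). ARF-104 lost chromosome 4 from 62920497 to 80797237 (-0.70), apart from its deletion at Cdkn2a, and chromosome 17 from 86721385 to 93273941 (-0.82).

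Measured X-linked genes such as Kdm6a, a histone demethylase, and Atrx lay in a segment at -0.43 in ARF-129. ARF-104 and ARF-112 shared small losses with equal first and last probes. On chromosome 13 they ran from 60475048 to 60642983 (-1.37 and -1.53) and from 64833006 to 64905371 (-1.42 and -1.57). The loss on chromosome 14, from 23546511 to 23683567 (-1.23 and -1.40), holds part of Anxa11, a calcium-binding protein gene. That on chromosome 19, from 36930674 to 37071715 (-0.51 and -0.63), holds Ide, the insulin-degrading enzyme. Ide belongs to the list of genes often variable between mouse strains. Whether these losses were inherited or arose in the tumours was not tested, since normal DNA of these mice was not analysed here.

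Deep loss over the Skint genes was seen in 4 of 5 tumours. Probes that fail with any DNA are argued against, since the probes of the deleted stretch had a mean of -0.21 in ARF-104, above the bound of -0.3. ARF-104 was already known to lie outside the pattern, so this restates it and rests on that array alone. An inherited deletion may be the source, as a hypothesis. The edges in ARF-112, ARF-128 and ARF-129 lay a median of 3 probes apart, exactly at the bound set for it after the edges were seen. Of 12 distances 7 were at most 3, and the highest was 18. The sparser design was left out of these distances. There the loss had equal first and last probes in ARF-110 and ARF-128 (111360552 to 111833982). Over the same span as the -0.21 of ARF-104, the mean was -1.52 in ARF-112 and -3.73 in ARF-128. It was -2.08 on the sparser array of ARF-128, so the depth in that tumour differed between arrays. Loss arising in the tumours was not tested, since normal DNA of these mice was not analysed here.

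Chromosome 19 was high in every tumour. GC content of the probes is argued against, since its mean stayed at 0.43 after the correction. Fewer copies in the shared reference, as the whole source, would give every tumour the same chromosome 19 minus chromosome 18. This spanned a range of 0.43 over tumours (0.19 to 0.62), above the bound of 0.2. The range rests on ARF-112 (0.19). The others lay between 0.45 and 0.62, within the bound, so the argument against the reference as the whole source rests on that tumour alone. A gain in the tumour cells may explain the high chromosome 19, as a hypothesis. No biological explanation was tested because the design holds a single group.

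Faf1 probes lay below the segment they are part of, by 0.16 against the probes 1 Mb either side. GC content is argued against as the whole source, since the gap was -0.15 (SE 0.03) after a correction that took away 0.01: this lay outside the 0.1 that GC content would allow by more than the SE, although it passed the bound of 0.15 set against it by less. A loss confined to Faf1 cannot be told apart from its absence here: Faf1 lay over 2 SE below its flanks in 1 of 4 tumours (ARF-104, -2.39 SE), which met the bound of at most 1 set beforehand against such a loss, but ARF-128 (-1.88) and ARF-129 (-1.89) lay just short, and the reading as open was settled on, after other readings, once these values were seen. The spread of other genes is argued against, as Faf1 lay at percentile 1.2 of 582 genes of like probe number (exact 95% interval 0.485 to 2.46). Such deviations correlated between tumours across these genes (r of 0.33 to 0.84 in 6 pairs, mean 0.60; genes are not independent replicates), so a property of the probes may contribute too.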
